A study of Arabidopsis thaliana with 27 samples.

How the data were processed

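Stamens of *Arabidopsis thaliana* were profiled on 1-colour Affymetrix ATH1 arrays, 1 array per sample, with biotin-labelled RNA. The groups were untreated *opr3* stamens, *opr3* stamens at 0.5, 2, 8 and 22 h after JA or OPDA at 0.03%, and stamens of the wild-type Ws background. The values deposited by the authors are MAS5 signal intensity per probe set on a linear scale, which the authors scaled on each array to a target of 125. The mean of each array with 2% trimmed at either end was 125 on all 27 arrays, the median signal lay between 47.5 and 56.9, and between 48.7% and 53.3% of the 22810 probe sets had a signal of at least 50. The software version, detection calls and background of the authors' processing are not stated in the labels. The array processing records were used for the scan day and the chip lot alone. OPDA 8 h replicate 1 and the Ws array have no such record here. Fits with scan day or chip lot as a block therefore left out OPDA 8 h replicate 1 and held 1 OPDA 8 h array. OPDA at 8 h has a replicate 1 and a replicate 3, and a replicate 2 was not analysed here.

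For JA at 0.5 h, replicates 1 and 2 had identical values at 100% of 22810 probe sets, where no other pair of arrays passed 0.94%, so the pair was counted once. The fit therefore held 25 arrays in 9 groups and not the 26 planned before the data were examined. Replicate 3 of JA at 2 h, titled *opr2*, was kept with its group. Signals were taken as log2(signal + 16), and the 14028 probe sets with a signal of at least 50 on at least 2 arrays were tested. One linear model with a mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, and eBayes with an intensity trend), with 16 residual degrees of freedom. The 13 comparisons were JA over untreated, OPDA over untreated and JA over OPDA at each of 4 times, and JA over OPDA averaged over the times. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. All tests were two-sided. Intervals are 95% intervals of the log2 change from the same fit, which reached a median of 0.37 to either side between groups of 3 arrays and 0.42 where a group held 2 arrays. The number of arrays limits the precision. The Ws array stayed outside the fit and its differences carry no test. Its counts used a change of at least 2-fold and a signal of at least 100, limits added after the data were seen.

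Probe sets were named by the platform's pairing of probe sets with loci and by RefSeq symbols. Of 22810 probe sets, 13513 were paired with 1 gene, 503 with several and 8794 with none, and 13436 of the first were matched to RefSeq. Genes named in the text follow a rule set before the data were examined: per comparison at 1 time, the 4 largest rises and 4 largest falls among called probe sets paired with 1 gene, with groups that do not overlap and a higher mean of at least 100. For Ws the 10 largest differences each way among such probe sets were named, and from each list up to 4 members with the smallest adjusted p. A list member with several probe sets is given by the brightest. The genes to be named in every case, among them OPR3, MYB21, MYB24 and VSP2, had no named probe set and were not analysed here.

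Before the data were examined, 25 gene lists with 297 members were fixed, of which 47 were named on the array. A further 23 families were added by symbol, 22 after the probe names but before any fold change was seen. The last of them, nuclear photosynthesis genes, was added after named genes were seen. The 24 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and with a correlation estimated per list, adjusted over the 24 lists. Of 55 calls over all comparisons, 12 held with an estimated correlation.

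Alternatives were pseudocounts of 1 and 64, no filter, a mean signal of at least 100, quantile normalization, scaling to the 75th percentile, a fit to the compared groups alone, replicate number, scan day or chip lot as a block, no intensity trend, array weights, a change of at least 2-fold, and each array left out in turn. Chosen after the data were seen were the duplicated array kept as 2 samples, its other replicate number or scan day in the blocks, median centring, the list tests under other scalings and blocks, each called list without each array in turn, relabellings and simulated sets that keep replicate numbers, the overlap of JA and OPDA without each treated array, and comparisons that share no array. The model was also tested on simulated data with 200 probe sets changed by set folds, after it had first been run on the arrays. With a change of 2-fold it called 76.1% of changed probe sets for JA at 22 h, 77.6% for OPDA at 22 h and 71.6% for JA at 0.5 h. A change of 1.5-fold was called in 43.3%, 34.3% and 20.9% of them. The noise of these data was drawn independently for each probe set and array, so deviations shared by arrays were not part of it. Sets simulated with no change, 100 in number and with the correlation between probe sets kept, had a call in at most 8 sets per comparison, and a single set held up to 2224 calls. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.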

Results

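Transcript levels were measured in stamens of *Arabidopsis thaliana* on 1-colour Affymetrix ATH1 arrays, each with 22810 probe sets. The *opr3* mutant lacks the reductase that turns the cyclopentenone 12-oxo-phytodienoic acid (OPDA) into precursors of jasmonic acid (JA), a cyclopentanone with a shorter side chain. Mutant stamens were taken untreated (3 arrays) or at 0.5, 2, 8 and 22 h after JA or OPDA, both at 0.03%. Each treated group held 3 arrays, apart from JA at 0.5 h and OPDA at 8 h, which held 2 distinct arrays each. For JA at 0.5 h, replicates 1 and 2 held the same value at 100% of probe sets, so the pair was counted as 1 sample. One array came from wild-type stamens of the Ws background. The title of the replicate 3 array of JA at 2 h names *opr2* and not *opr3*, and it was kept in its group. Values were MAS5 signals scaled by the authors to a common target, with a trimmed mean of 125 on each array and a median between 47.5 and 56.9 over 27 arrays. The number of arrays limits the precision: the 95% interval of a log2 change reached a median of 0.37 to either side between groups of 3 arrays and 0.42 where 1 group held 2. Fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. The labels list no mock-treated arrays, so a change from the untreated arrays also holds time since treatment and harvest. Nothing in the labels says that replicates came from separate plants, so p-values measure the spread between these samples.

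The first question was which stamen transcripts responded to JA, and when. At 0.5 h the JA-responsive factor ORA47 (AT1G74930), a regulator of JA synthesis, rose from a signal of 9.3 ± 6.12 (SD, n = 3) to 122 ± 13.5 (n = 2), a log2 change of 2.47 (limma adjusted p = 0.0011). JOX2 (AT5G05600), an oxygenase that hydroxylates JA, rose by 2.09 (limma adjusted p = 0.0011), from 25.1 ± 18 to 148 ± 31.0. OPCL1 (AT1G20510), a CoA ligase of JA synthesis, rose by 1.79 (limma adjusted p = 4.4e-05), and AT3G50280 by 1.75 (limma adjusted p = 0.028). In the list of JA catabolism genes, 1 of the 3 tested probe sets was called higher, JOX2, also when adjusted over the list alone. The list test was passed (limma camera adjusted p = 0.00011, and adjusted p = 0.0068 with an estimated correlation), but with JOX2 as 1 of 3 members it is not separate from the rise given above. Of the 10 genes fixed for this list only JOX2, JOX4 and JRG21 were tested, so here and below it does not stand for all of JA catabolism. An unadjusted p under 0.05 was reached by 357 of 14028 tested probe sets, a smaller share than the 0.05 that chance gives. In all, 16 were called higher and 0 lower by limma. Without replicate 3 of JA at 0.5 h, 16 were called higher and 3 lower. Without replicate 1, 7 were called and ORA47, JOX2 and AT3G50280 lost their calls, and a fit to these 2 groups alone called 0. With scan day as a block and the duplicated array on the other of its days, 9 were called, without ORA47 and JOX2. AT3G50280 also lost its call without any 1 of the untreated arrays.

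At 2 h after JA, JOX2 reached 512 ± 39.4 (n = 3), a log2 change of 3.79 (limma adjusted p = 4.2e-09). AT1G54020, AT5G12890 and AT2G32150 rose by 3.31, 3.0 and 2.89. The list of UDP-glycosyltransferases, enzymes that attach sugars to small molecules, was higher (limma camera adjusted p = 2.5e-07, and adjusted p = 0.00082 with an estimated correlation), with 4 of 19 members called higher and 0 lower. UGT74B1, of glucosinolate synthesis, rose from 81.4 ± 22.6 to 426 ± 97.5 (n = 3 each), and UGT76E12 and UGT87A2 rose by 1.74 and 1.21. JA catabolism genes were also higher as a list (limma camera adjusted p = 1.3e-08, and adjusted p = 0.00028 with an estimated correlation), with 1 of 3 called, JOX2, and 3 of 3 higher when adjusted over the list alone. TBL wall acetylation genes (2 of 12 higher, among them TBL26 with 1.74) and SWEET sugar transporters (2 of 14 higher, among them SWEET4 with 1.06) passed the list test at adjusted p = 0.012 and 0.038 (limma camera), but had adjusted p = 0.12 and 0.30 with an estimated correlation. SWEET transporters also failed it under quantile normalization (adjusted p = 0.079) and without untreated replicate 1 or 3 or JA 2 h replicate 1 or 2 (0.092 to 0.15), and TBL genes without JA 2 h replicate 2 (0.058).

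Among the falls at 2 h, the dehydrin LTI30 (AT3G50970) went from 594 ± 256 to 205 ± 42.6 (n = 3 each; log2 change -1.41, limma adjusted p = 0.015). The clock gene GI (log2 change -1.0), the photosystem antenna gene LHCB4.2 (-0.95) and AT5G49990 (-0.73) also fell. The 9 nuclear photosynthesis genes, with LHCB4.2 as the 1 member called, had limma camera adjusted p = 0.031, and adjusted p = 0.52 with an estimated correlation. This list was added after named genes were seen, and LHCB4.2 is a named gene. Here and below its list test is therefore no independent support. Autophagy genes had limma camera adjusted p = 0.028 with 0 of 10 members called by limma, and adjusted p = 0.40 with an estimated correlation. The first list lost its call without untreated replicate 2 or 3 or JA 2 h replicate 2 (adjusted p = 0.078 to 0.36), and the second without untreated replicate 2 or JA 2 h replicate 2 or 3 (0.075 to 0.18). In all, 280 probe sets were called higher and 32 lower, and array weights raised the total of 312 to 491. LTI30 lost its call without untreated replicate 2 or JA 2 h replicate 3, the array titled *opr2*, AT5G49990 without untreated replicate 1 or 2 or JA 2 h replicate 1, and GI and LHCB4.2 in a fit to these 2 groups alone. Within the 2 scan days that held both groups, the median log2 change was 1.21 and 0.99 over the rises and -0.91 and -0.60 over the falls. Medians within scan days, here and below, are over probe sets called on the same arrays, a choice that favours the called direction.

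At 8 h, JOX2 stood at 862 ± 93.5 (n = 3; log2 change 4.52, limma adjusted p = 1.0e-10). AT2G18480 rose from 55.8 ± 21 to 968 ± 69.6 (log2 change 3.81), AT5G12890 by 3.75 and AT3G25290 by 3.28. All 3 tested JA catabolism genes were higher, over all genes and adjusted over the list alone: JOX2, JOX4 (log2 change 1.81) and JRG21 (1.21), with limma camera adjusted p = 1.4e-06, and adjusted p = 0.0013 with an estimated correlation. ADPG1, a polygalacturonase of anther opening and the 1 tested member of the dehiscence list, rose from 160 ± 62.6 to 1183 ± 383 (n = 3 each; limma adjusted p = 1.4e-06). Of 19 UDP-glycosyltransferases, 4 were higher, led by UGT74D1 (log2 change 2.64), and 1 was lower, UGT74F1 (-1.33), with limma camera adjusted p = 0.0037, and adjusted p = 0.051 with an estimated correlation. Among 17 pollen-expressed genes, ANX1 (1.3) and NET2D (1.15) were higher, and the list had limma camera adjusted p = 0.0037, and adjusted p = 0.59 with an estimated correlation. Its median log2 change of 0.41 rested on JA 8 h replicate 2: without that array it was 0.10 (limma camera adjusted p = 0.32), and it was 0.88 on the scan day of that array and -0.06 on the other day.

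LTI30 fell further by 8 h, to 24.2 ± 3.44 (n = 3; log2 change -3.85, limma adjusted p = 1.9e-08). AT1G11210 fell from 123 ± 16.6 to 5.0 ± 1.68, and AT2G05540 (log2 change -2.31) and LEA (AT2G21490), a late embryogenesis abundant protein gene (-2.48), fell as well. In all, 669 probe sets were called higher and 738 lower, a balance that turned to more rises under quantile normalization (745 and 608), scaling to the 75th percentile (749 and 568) and median centring (796 and 505), and with a change of at least 2-fold (337 and 173). The total of 1407 became 861 without untreated replicate 1, 896 without JA 8 h replicate 2, 650 in a fit to these 2 groups alone, and 2146 with scan day as a block. Within the 2 scan days that held both groups, the medians were 1.2 and 0.81 over the rises and -0.87 and -0.57 over the falls.

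At 22 h the largest rise among the genes that met the naming rule was that of JOX4 (AT2G38240), a relative of JOX2, from 13.7 ± 6.78 to 3219.7 ± 871 (SD, n = 3 each; log2 change 6.76, limma adjusted p = 4.8e-13). The sugar transporter SWEET14 (AT4G25010) rose from 20.8 ± 12.6 to 3835 ± 945 (log2 change 6.73), AT3G60780 by 5.53 and AT4G24380 by 5.16, to 7893 ± 1760. The mean of SWEET14 after JA was 23.2 at 0.5 h, 12.7 at 2 h and 9.5 at 8 h. Of 3 JA catabolism genes, JOX4 and JOX2 (log2 change 3.27) were higher, over all genes and adjusted over the list alone, with limma camera adjusted p = 0.00087, and adjusted p = 0.025 with an estimated correlation. ADPG1 stood at 1551.7 ± 259 (log2 change 3.21, limma adjusted p = 5.4e-08). The JA methyltransferase JMT, 1 of 2 tested JA biosynthesis genes, rose from 148 ± 68.0 to 578 ± 167, and the terpene synthases TPS24 and TPS11, both tested members of their list, rose by 2.74 and 1.31. The thionin THI2.1, the 1 tested JA marker, rose by 1.78, and the auxin-conjugating enzyme GH3.3 (AT2G23170) by 5.14, from 10.9 ± 14.3 to 897 ± 337. These 4 lists gave the same counts when adjusted over the list alone: 1 of 1 for dehiscence, 1 of 2 for JA biosynthesis, 2 of 2 for terpene synthases and 1 of 1 for JA markers. With 1 or 2 tested members this adjustment is looser here than that over all genes. A called member therefore keeps its call, which adds no support.

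Pollen-expressed genes were higher as a list at 22 h after JA (limma camera adjusted p = 2.1e-05, and adjusted p = 0.28 with an estimated correlation), with 12 of 17 called higher and 1 lower. Their median log2 change was 1.60 on one shared scan day and 0.69 on the other, and 0.99 without JA 22 h replicate 2 against 1.31 with all arrays. Among them PLIM2a, which binds actin in pollen, went from 443 ± 298 to 3319.7 ± 1140 (n = 3 each). ANX2 and ANX1, receptor kinases that keep pollen tubes intact, rose by 2.79 and 1.97, while AtVEX1 fell from 2300.4 ± 305 to 933 ± 203. Of the 4 pollen genes in the list fixed first, 3 were higher and 1 lower, over all genes and adjusted over the list alone, with limma camera adjusted p = 0.088. GH9 endoglucanases, which cut wall glucans, had 6 of 10 members higher and 2 lower (limma camera adjusted p = 0.021, and adjusted p = 0.12 with an estimated correlation), led by GH9B11 with a rise of 4.11. Expansins and xyloglucan endotransglucosylases had 4 of 15 higher and 1 lower (limma camera adjusted p = 0.012, and adjusted p = 0.11 with an estimated correlation), led by EXPB5, from 125 ± 89.5 to 1971 ± 727. Tubulins had 5 of 7 higher and 0 lower (limma camera adjusted p = 0.0029, and adjusted p = 0.11 with an estimated correlation), among them TUA1 (log2 change 1.94) and TUB9 (1.15). RALF-like peptides had 4 of 8 higher and 0 lower (limma camera adjusted p = 0.015, and adjusted p = 0.091 with an estimated correlation), among them RALFL26, with a rise of 3.36. AGAMOUS-like factors had 4 of 11 higher and 0 lower (limma camera adjusted p = 0.047), with adjusted p = 0.31 with an estimated correlation, 0.059 under quantile normalization, and 0.080 and 0.089 without untreated replicate 3 and JA 22 h replicate 2. SWEET transporters went both ways, with 5 of 14 higher and 4 lower (limma camera adjusted p = 0.088): SWEET13 rose from 75.5 ± 4.05 to 2016 ± 469, while SWEET8 fell from 584 ± 249 to 122 ± 19.4.

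The falls at 22 h were led by ATA27 (AT1G75940), an anther gene of the beta-glucosidase family, from 454 ± 268 to 5.0 ± 5.69 (n = 3 each; log2 change -4.28, limma adjusted p = 5.1e-05). LEA (log2 change -3.89), AT2G05540 (-3.63) and AT1G23240 (-3.48) also fell, the last from 2892 ± 887 to 281 ± 168. Without JA 22 h replicate 2, LEA fell by 2.91 and AT1G23240 by 2.84. EXL5, the 1 tested member of the tapetum and pollen coat list, was called and fell by 2.12, and an adjustment over this 1 member adds no support. Of 9 nuclear photosynthesis genes, 5 were called lower and 0 higher, among them LHCB4.2 (log2 change -1.43), RCA, the activase of Rubisco (-0.80), and LHCB4.3 (-0.69), but the list had limma camera adjusted p = 0.059. In the photosynthesis list fixed first, 1 of 3 was lower, RCA, over all genes and adjusted over the list alone (limma camera adjusted p = 0.36). In all, 1859 probe sets were called higher and 3693 lower, and 1038 and 767 of these changed at least 2-fold. The median log2 change over all tested probe sets was -0.21, and it was -0.11 under quantile normalization and -0.10 under scaling to the 75th percentile. The share of rises among called probe sets was 33.5%, and it was 40.7% under quantile normalization, 45.3% under scaling to the 75th percentile, 50.4% (2266 rises and 2230 falls) after median centring and 57.5% with a change of at least 2-fold. Within the 2 shared scan days, the medians over the 5552 called were 1.42 and 0.81 for rises and -0.80 and -0.47 for falls.

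The second question was what OPDA, which *opr3* stamens cannot reduce by the route that OPR3 serves, did over the same times. At 0.5 h JOX2 stood at 13.4 ± 10.8 (n = 3) after OPDA against 25.1 ± 18 in untreated stamens (limma adjusted p = 1.0), and OPCL1 at 72.0 ± 9.96 (limma adjusted p = 1.0). ORA47 stood at 53.1 ± 4.69 against 9.3 ± 6.12, a log2 difference of 1.47 with a 95% interval from 0.80 to 2.14, which missed the threshold over all genes (limma adjusted p = 0.56). JOX2 was at 65.3 ± 18.4 at 2 h (limma adjusted p = 0.61) and 49.3 ± 15.0 (n = 2) at 8 h (limma adjusted p = 1.0). The probe sets called by limma were 1 at 0.5 h, 3 at 2 h and 0 at 8 h, against 329, 286 and 391 at an unadjusted p under 0.05. Each of these last counts is a smaller share of the 14028 tested than the 0.05 that chance gives. They show no excess, but a share under 0.05 does not show that no transcript changed. The 4 called were higher and were chosen for mention after their values were seen. AT5G35735 rose at 2 h, from 14.8 ± 11.3 to 84.9 ± 44.2 (n = 3 each; limma adjusted p = 0.013). The other 3 were paired with no gene and stood at 113 ± 31.5 against 41.1 ± 4.20 at 0.5 h, and at 96.1 ± 45.8 against 11.2 ± 4.09 and 96.7 ± 7.71 against 25.5 ± 18.7 at 2 h. A fit to the compared groups alone called 0 at 0.5 h and 0 at 2 h. Without untreated replicate 1, OPDA 0.5 h replicate 2 or OPDA 0.5 h replicate 3 the call at 0.5 h was lost, and without untreated replicate 1, OPDA 2 h replicate 2 or OPDA 2 h replicate 3 there were 0 calls at 2 h. Without untreated replicate 3 there were 2 at 0.5 h and 6 at 2 h, and without untreated replicate 2 there was 1 at 2 h.

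Some lists passed limma's camera test at these early times with no member called over all genes. JA catabolism genes were higher at 2 h (limma camera adjusted p = 0.043, and adjusted p = 0.15 with an estimated correlation), with JOX2 called when adjusted over the list alone, but not without untreated replicate 1 or 3 or OPDA 2 h replicate 1 or 3 (limma camera adjusted p = 0.062 to 0.30). Chloroplast-encoded genes were lower at 0.5 h (limma camera adjusted p = 0.022), with 0 of 49 called and adjusted p = 0.93 with an estimated correlation. Their median log2 change of -0.33 became 0.13 without untreated replicate 3 and 0.10 without OPDA 0.5 h replicate 1, and these arrays and OPDA 0.5 h replicate 2 each ended the call (limma camera adjusted p = 0.98, 0.86 and 0.60). The median over these 49 genes was highest on the replicate 3 array in 9 of 9 groups, all scanned on 1 day. Gene by gene, the log2 rise of that array over the mean of the group's other arrays had a median of 1.11 to 1.60. At 8 h, 6 lists were higher: nuclear photosynthesis genes (3.5e-05), aldehyde dehydrogenases (0.014), UDP-glycosyltransferases (0.015), photosynthesis genes (0.021), glutathione S-transferases (0.038) and cell wall loosening genes (0.038), each with its limma camera adjusted p. All 6 had adjusted p = 0.20 with an estimated correlation and lost their call without untreated replicate 1 (0.11 to 0.34). They also lost their call with scan day as a block. That fit left out OPDA 8 h replicate 1 and held 1 OPDA 8 h array, so the loss cannot be put down to scan day alone. Without OPDA 8 h replicate 1 the lists of UDP-glycosyltransferases, glutathione S-transferases and aldehyde dehydrogenases lost it (0.13 to 0.35), and without replicate 3 those of photosynthesis and cell wall loosening genes (0.18 and 0.30). Adjusted over the list alone, 0 of 3 photosynthesis genes and 0 of 3 cell wall loosening genes were called at 8 h.

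At 22 h after OPDA, stamens differed from untreated ones in many transcripts. PIPK11 (AT1G01460), a phosphatidylinositol phosphate kinase, rose from 18.4 ± 26.1 to 200 ± 146 (n = 3 each; log2 change 2.67, limma adjusted p = 0.014), and AT59 (AT1G14420), of the pectate lyase family, from 98.2 ± 63.6 to 637 ± 330. AT1G11770 rose by 2.62 and AT2G46300 by 2.54. Pollen-expressed genes were higher as a list (limma camera adjusted p = 2.0e-08, and adjusted p = 0.19 with an estimated correlation), with 9 of 17 called higher and 0 lower, among them PLIM2a (log2 change 2.25), ANX2 (1.67), ANX1 (1.66) and SETH3 (0.96). The list's median log2 change was 0.77 with all arrays and 0.57 without OPDA 22 h replicate 2 (limma camera adjusted p = 4.6e-06), and it was 1.32 on the scan day of that array and 0.40 on the other shared day. Of the 4 pollen genes in the list fixed first, 3 were higher, over all genes and adjusted over the list alone (limma camera adjusted p = 0.0015, and adjusted p = 0.12 with an estimated correlation). TBL genes had 5 of 12 higher (limma camera adjusted p = 0.0028, and adjusted p = 0.12 with an estimated correlation), among them TBL20, from 96.7 ± 16.3 to 275 ± 103. JOX2 rose to 96.9 ± 14.5 and was the 1 JA catabolism gene of 3 called, also when adjusted over the list alone (limma camera adjusted p = 0.036, and adjusted p = 0.12 with an estimated correlation). ADPG1 rose by 1.3, to 401 ± 56.7. RALF-like peptides (2 of 8 higher), AGAMOUS-like factors (1 of 11) and tubulins (2 of 7) passed limma's camera test at adjusted p = 0.032, 0.029 and 0.032, and had adjusted p = 0.12, 0.26 and 0.21 with an estimated correlation. Tubulins also missed the threshold under quantile normalization (adjusted p = 0.094). Without an array, tubulins (untreated replicate 1 or OPDA 22 h replicate 3), JA catabolism (untreated replicate 3 or OPDA 22 h replicate 1 or 3), RALF-like peptides (untreated replicate 3 or OPDA 22 h replicate 3) and AGAMOUS-like factors (untreated replicate 3 or OPDA 22 h replicate 2) lost their calls, with limma camera adjusted p of 0.076 to 0.12.

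The falls at 22 h after OPDA included ATA27, to 17.3 ± 15.9 (n = 3; log2 change -3.68, limma adjusted p = 0.0035). AT5G17340 (log2 change -3.22), AT4G37900 (-3.01) and AT3G50570 (-2.70) also fell, and JMT fell by 1.26, to 52.0 ± 29.7. JOX4 (26.2 ± 17.8), SWEET14 (23.8 ± 19.6) and GH3.3 (3.6 ± 3.13) had adjusted p = 0.40, 0.94 and 0.54 (limma). In all, 799 probe sets were called higher and 829 lower, and 428 and 212 of these changed at least 2-fold. The balance also turned to more rises under quantile normalization (842 and 759), scaling to the 75th percentile (837 and 720) and median centring (907 and 607). The total of 1628 became 213 without untreated replicate 1, 377 without untreated replicate 2, 294 without OPDA 22 h replicate 2 and 469 in a fit to these 2 groups alone, while it rose to 2770 with scan day as a block. PIPK11, AT1G11770 and AT59 lost their calls without each of these 3 arrays, and the latter pair also without OPDA 22 h replicate 3. Over the 1628 called, the medians were 1.58 for rises and -1.04 for falls on the scan day that held untreated replicates 1 and 2 and OPDA 22 h replicate 2, and 0.60 and -0.40 on the other shared day.

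**Figure D1:**
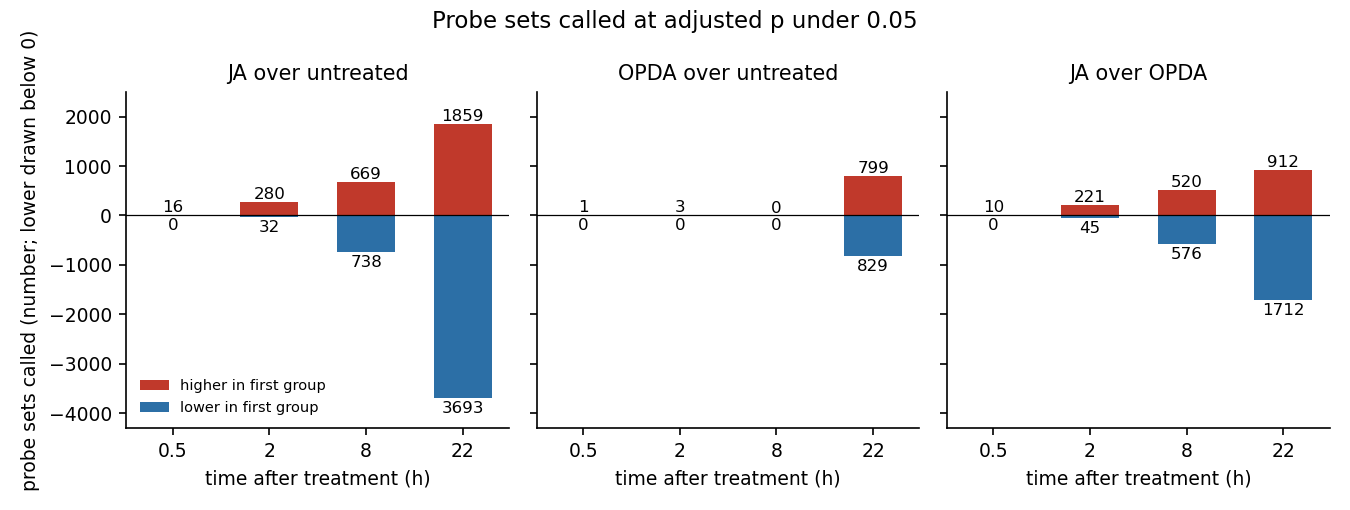
Bars show the number of probe sets called at a limma adjusted p under 0.05, higher above 0 and lower below 0, against time after treatment in h, for JA over untreated, OPDA over untreated and JA over OPDA. The largest bars are the 1859 rises and 3693 falls at 22 h after JA, and OPDA over untreated has 1 call at 0.5 h, 3 at 2 h and 0 at 8 h.

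The third question was how JA and OPDA, given at the same concentration, differed at each time. At 0.5 h JOX2 was higher after JA than after OPDA, 148 ± 31.0 (n = 2) against 13.4 ± 10.8 (n = 3), a log2 difference of 2.52 (95% interval 1.89 to 3.16, limma adjusted p = 0.00016). OPCL1 was higher by 1.25, 199 ± 75.2 against 72.0 ± 9.96 (limma adjusted p = 0.0070). ORA47 had a log2 difference of 1.0 with a 95% interval from 0.25 to 1.75 (limma adjusted p = 1.0). JA catabolism genes were higher after JA as a list (limma camera adjusted p = 3.6e-06, and adjusted p = 0.0018 with an estimated correlation), with 1 of 3 called, also when adjusted over the list alone. Chloroplast-encoded genes were higher after JA (limma camera adjusted p = 0.043), with 0 of 49 called, adjusted p = 0.99 with an estimated correlation and a median log2 difference of 0.33. Without JA 0.5 h replicate 3 they were lower (-0.46, limma camera adjusted p = 0.024), and without OPDA 0.5 h replicate 1 or 2 the call was lost (-0.05 and 0.17, adjusted p = 0.96 and 0.54). An unadjusted p under 0.05 was reached by 316 probe sets, a smaller share of those tested than the 0.05 that chance gives. In all, 10 were called higher and 0 lower by limma. Without JA 0.5 h replicate 1 there were 5 and without replicate 3 there were 18, 13 higher and 5 lower, and a fit to these 2 groups alone called 3 and not JOX2 or OPCL1. OPCL1 also lost its call without JA 0.5 h replicate 1 or OPDA 0.5 h replicate 3.

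At 2 h AT5G12890 was higher after JA, 336 ± 18.5 against 33.5 ± 10.4 (n = 3 each; log2 difference 2.85, limma adjusted p = 2.6e-09). NAI1 (AT2G22770), a factor needed for endoplasmic reticulum bodies, was higher by 2.84, 191 ± 66.8 against 12.3 ± 6.06, JOX2 by 2.72 and AT2G32150 by 2.53. The lists higher after JA with either correlation were UDP-glycosyltransferases (3 of 19 higher, limma camera adjusted p = 4.0e-07), JA catabolism (1 of 3 higher, and 3 of 3 adjusted over the list alone, limma camera adjusted p = 8.9e-07) and RALF-like peptides (1 of 8 higher, RALFL33 with 0.80, limma camera adjusted p = 0.0044). With an estimated correlation their adjusted p was 0.00076, 0.00076 and 0.020. Within UDP-glycosyltransferases, UGT76E12 was higher by 2.05, UGT74B1 by 1.74 and UGT87A2 by 1.07. Lower after JA were ARL (log2 difference -1.47, but -0.91 without OPDA 2 h replicate 3, where it stood at 305.9 against 80.4 and 90.5), LTI30 (-1.46), AT1G56220 (-1.04) and AT4G28240 (-0.85). Nuclear photosynthesis genes were lower as a list, with 1 of 9 called (limma camera adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation). SWEET transporters and aldehyde dehydrogenases, each with 0 members called by limma, both had limma camera adjusted p = 0.048, adjusted p = 0.36 with an estimated correlation, and 0.12 under quantile normalization. Nuclear photosynthesis genes lost their call without JA 2 h replicate 2 or OPDA 2 h replicate 3 (limma camera adjusted p = 0.23 and 0.24), SWEET transporters without JA 2 h replicate 1 or 2 or OPDA 2 h replicate 2 or 3 (0.093 to 0.34), and aldehyde dehydrogenases without JA 2 h replicate 1 or 2 or OPDA 2 h replicate 1 or 2 (0.051 to 0.23). In all, 221 probe sets were called higher and 45 lower, with medians of 1.04 to 1.17 for rises and -0.94 to -0.59 for falls within 3 scan days. With replicate number as a block, 348 were called higher and 118 lower. AT1G56220 lost its call without JA 2 h replicate 1 or 2 or OPDA 2 h replicate 2 or 3, LTI30 without JA 2 h replicate 3 or OPDA 2 h replicate 1 or 3, and ARL in a fit to these 2 groups alone.

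At 8 h JOX2 stood at 862 ± 93.5 (n = 3) after JA and 49.3 ± 15.0 (n = 2) after OPDA, a log2 difference of 3.76 (95% interval 3.13 to 4.40, limma adjusted p = 2.2e-08). AT5G12890 was higher after JA by 3.70, AT2G18480 by 3.59, AT3G25290 by 3.21 and ADPG1 by 2.68. All 3 JA catabolism genes were higher, over all genes and adjusted over the list alone (limma camera adjusted p = 1.1e-05, and adjusted p = 0.0027 with an estimated correlation). Pollen-expressed genes had 3 of 17 higher, PLIM2a (2.20), ANX1 (1.32) and NET2D (1.25), with limma camera adjusted p = 0.00015, and adjusted p = 0.55 with an estimated correlation. The list's median log2 difference was 0.60, but 0.26 without JA 8 h replicate 2 (limma camera adjusted p = 0.022), 0.50 without OPDA 8 h replicate 1 (adjusted p = 0.0028) and 0.16 within the 1 scan day that held both groups. LTI30 was lower after JA, 24.2 ± 3.44 against 749 ± 175 (log2 difference -4.23, limma adjusted p = 3.8e-08), as were AT1G11210 (-2.78), LEA (-2.68) and AT2G05540 (-2.56). Nuclear photosynthesis genes had 1 of 9 lower, LHCB4.3 (-0.65), with limma camera adjusted p = 0.0062, adjusted p = 0.55 with an estimated correlation, and 0.068 and 0.053 without JA 8 h replicate 1 and OPDA 8 h replicate 3. In all, 520 probe sets were called higher and 576 lower, with medians of 0.99 and -0.72 within the 1 shared scan day. The balance turned to more rises under quantile normalization (525 and 475), scaling to the 75th percentile (579 and 446) and median centring (591 and 409), and with a change of at least 2-fold (323 and 181). The total became 616 without JA 8 h replicate 2 and 448 in a fit to these 2 groups alone. It also fell without either OPDA 8 h array and with scan day as a block, a fit that left out OPDA 8 h replicate 1. Those fits held 1 OPDA 8 h array, so an effect of scan day cannot be told from that of the lost array. LEA lost its call without JA 8 h replicate 2 and without either OPDA 8 h array.

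At 22 h SWEET14 was at 3835 ± 945 after JA and 23.8 ± 19.6 after OPDA (n = 3 each), a log2 difference of 6.67 (95% interval 5.88 to 7.46, limma adjusted p = 1.3e-11). JOX4 differed by 6.32, GH3.3 by 5.49 and AT1G76240 by 4.90. JMT was at 578 ± 167 after JA and 52.0 ± 29.7 after OPDA, and ADPG1 at 1551.7 ± 259 and 401 ± 56.7 (log2 difference 1.91). JA catabolism genes had 2 of 3 higher, also when adjusted over the list alone (limma camera adjusted p = 0.0034, and adjusted p = 0.035 with an estimated correlation). GH9 endoglucanases had 3 of 10 higher and 1 lower, among them GH9B11 (3.77) and GH9C2 (0.99), with limma camera adjusted p = 0.035, and adjusted p = 0.23 with an estimated correlation. Expansins and xyloglucan endotransglucosylases (1 of 15 higher) and tubulins (0 of 7 called by limma) had limma camera adjusted p = 0.046 and 0.035, and adjusted p = 0.23 and 0.25 with an estimated correlation. Under quantile normalization they had adjusted p = 0.056 and 0.10. All 3 of these lists lost their calls without JA 22 h replicate 2 or OPDA 22 h replicate 1, and expansins also without OPDA 22 h replicate 3 (limma camera adjusted p = 0.058 to 0.13). Among 17 pollen-expressed genes 2 were higher and 1 lower, and the list's median log2 difference was 0.23, and 0.09 to 0.39 within 3 scan days (limma camera adjusted p = 0.18, and adjusted p = 0.79 with an estimated correlation). Among those not called, ACT12 had a log2 difference of 0.03 (95% interval -0.36 to 0.43), ANX1 of 0.31 (-0.38 to 1.01) and PLIM2a of 0.75 (-0.50 to 2.00). The 2 called higher after JA were SETH3 and NET2D, by 0.87 and 0.64. In the pollen list fixed first, 0 of 4 were higher and 1 was lower, AtVEX1 (-1.59), while adjusted over the list alone 1 was higher and 1 lower (limma camera adjusted p = 0.96).

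Lower after JA than after OPDA at 22 h were AT2G05540, 19.4 ± 12.6 against 581.5 ± 42.9 (n = 3 each; log2 difference -4.15, limma adjusted p = 1.5e-07), LEA (-2.80, but -1.83 without JA 22 h replicate 2), LTI30 (-2.42) and AT5G14940 (-2.38). Nuclear photosynthesis genes had 6 of 9 lower and 0 higher, among them LHCB4.3 (-0.84), LHCB4.2 (-0.79), RCA (-0.76) and PSAN (-0.74), with limma camera adjusted p = 0.0085, and adjusted p = 0.29 with an estimated correlation. In the photosynthesis list fixed first, 2 of 3 were lower, and 3 of 3 adjusted over the list alone (limma camera adjusted p = 0.060). Aldehyde dehydrogenases had 4 of 8 lower, led by ALDH11A3, 239 ± 72.4 against 562 ± 55.5, with limma camera adjusted p = 0.015, and adjusted p = 0.23 with an estimated correlation. In all, 912 probe sets were called higher and 1712 lower, a share of 34.8% higher, and the total of 2624 became 1601 in a fit to these 2 groups alone. That share was 39.2% under quantile normalization, 45% under scaling to the 75th percentile, 46.1% after median centring and 52.8% with a change of at least 2-fold. Within 3 scan days the medians ran from 0.86 to 1.13 for rises and from -0.79 to -0.60 for falls.

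Averaged over the 4 times, AT5G12890 was higher after JA by 2.23 (limma adjusted p = 5.1e-13), JOX2 by 2.68 and JOX4 by 2.30, and LTI30 was lower by a log2 difference of -2.06. JA catabolism genes had 3 of 3 higher, also when adjusted over the list alone (limma camera adjusted p = 1.6e-07, and adjusted p = 0.00061 with an estimated correlation). UDP-glycosyltransferases had 4 of 19 higher and 2 lower, GH9 endoglucanases 3 of 10 higher and 1 lower, RALF-like peptides 2 of 8 higher and pollen-expressed genes 1 of 17 higher and 1 lower. Their limma camera adjusted p was 0.034, 0.025, 0.025 and 0.012, and with an estimated correlation their adjusted p was 0.14, 0.14, 0.13 and 0.45. Without JA 0.5 h replicate 3, JA 2 h replicate 3, JA 8 h replicate 1 or 3 or OPDA 22 h replicate 2, UDP-glycosyltransferases lost their call (limma camera adjusted p = 0.050 to 0.060). Nuclear photosynthesis genes had 5 of 9 lower (limma camera adjusted p = 0.00091, and adjusted p = 0.31 with an estimated correlation). In all, 790 probe sets were called higher and 1266 lower, and 148 of the 2056 changed at least 2-fold, 133 higher and 15 lower. More probe sets were also higher than lower under scaling to the 75th percentile (924 and 877) and median centring (950 and 841), but not under quantile normalization (835 and 1022).

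**Figure D2:**
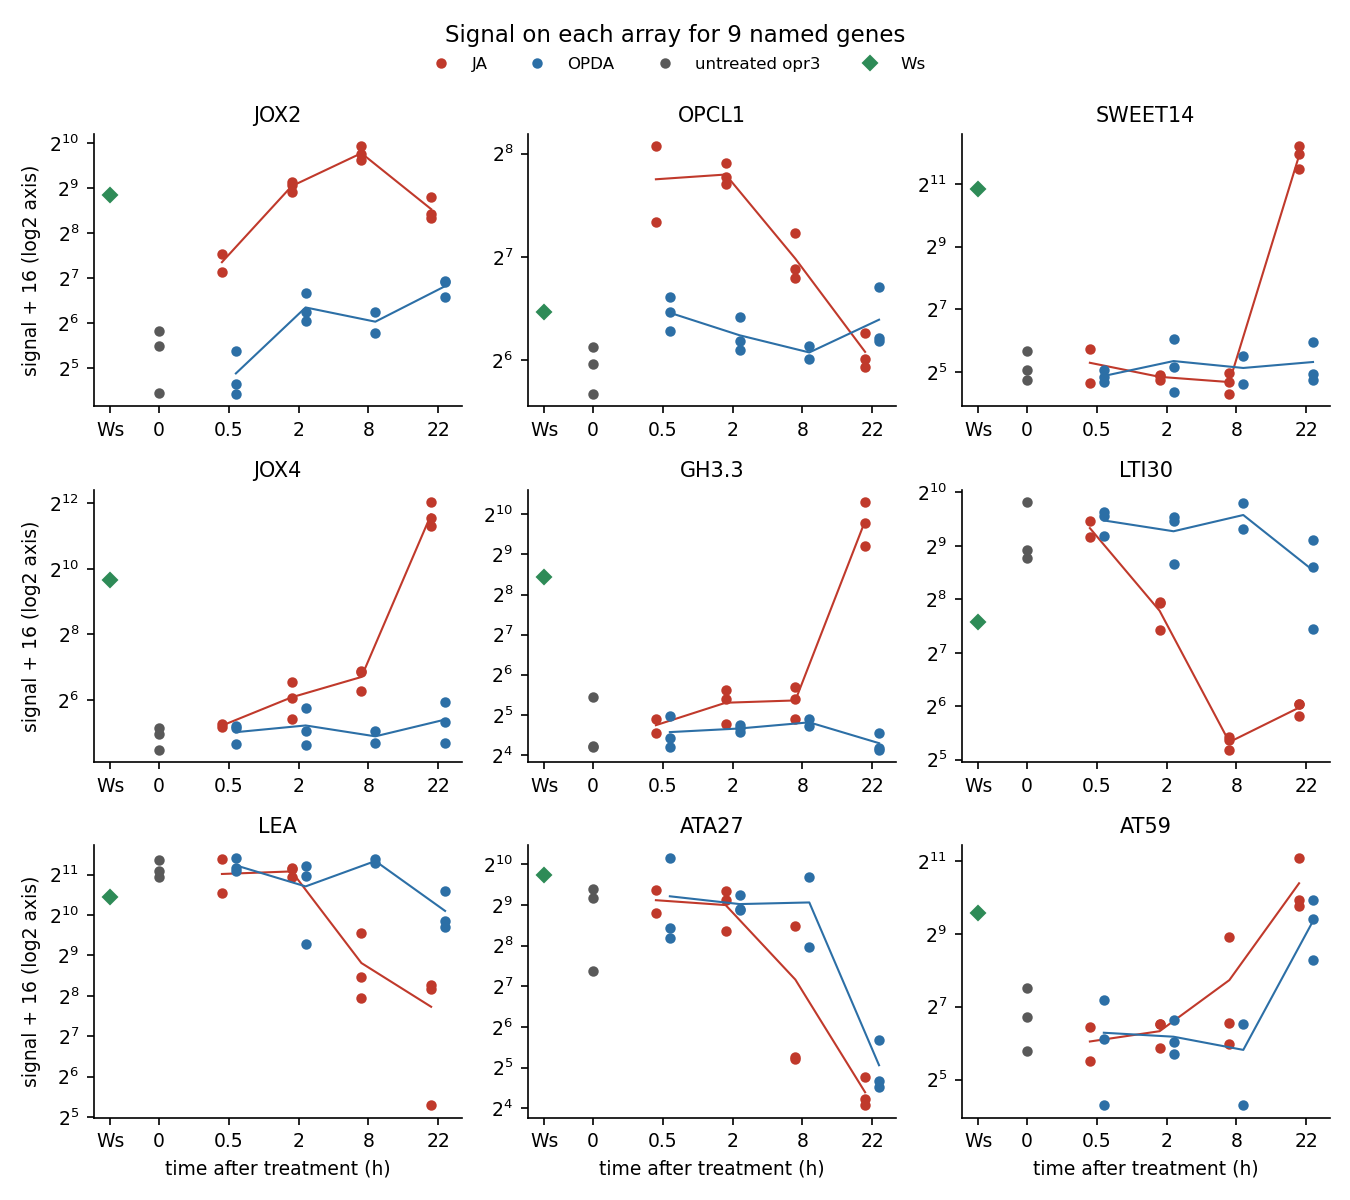
Points show the signal plus 16 on each array, on a log2 axis, for 9 named genes against time after treatment in h, with lines through the means after JA and after OPDA, untreated *opr3* arrays at 0 h and the Ws array at the left. SWEET14, JOX4 and GH3.3 reach means of 3835, 3219.7 and 897 at 22 h after JA and lie at 23.8, 26.2 and 3.6 at 22 h after OPDA.

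The fourth question was how far the changes after JA and after OPDA ran together. At 22 h, ANX1, ANX2, PLIM2a, ADPG1 and JOX2 were called higher after both compounds, and ATA27 was called lower after both. Of all tested probe sets, 640 were called higher after both, where 106 would be expected if the calls were independent, 627 lower after both (218 expected) and 38 in opposite directions, JMT among them. Across probe sets, which are not independent replicates, the log2 changes at 22 h had Pearson's r = 0.69 and Spearman's rho = 0.62. Both changes are measured against the same 3 untreated arrays, and 100 simulated sets with no change gave r from -0.42 to 0.92 with a mean of 0.45. Their covariance was 0.276, against a mean of 0.026 and at most 0.108 in the simulated sets. At 0.5, 2 and 8 h r was 0.50, 0.39 and 0.14, against simulated means of 0.44, 0.51 and 0.46. The number called the same way at 22 h, 1267, became 177, 305 or 245 without untreated replicate 1, untreated replicate 2 or OPDA 22 h replicate 2. Without OPDA 8 h replicate 3, r at 8 h was -0.01.

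The fifth question was how untreated *opr3* stamens differed from those of the wild type, for which 1 array gives values without a test. SWEET14 stood at 1811 on the Ws array against 20.8 ± 12.6 (SD, n = 3) in *opr3*, JOX4 at 799 against 13.7 ± 6.78, AT4G24380 at 4832 against 203 ± 28.3 and GH3.3 at 332.5 against 10.9 ± 14.3. AT3G60780, AT1G76240, AT3G17060, AT5G65380, JOX2 and AT3G43960 were higher in Ws by log2 differences of 4.59, 4.31, 3.89, 3.82, 3.6 and 3.53. Of 17 pollen-expressed genes, 16 lay above the range of the *opr3* arrays, among them PLIM2a at 2236.7 against 443 ± 298, and all 3 JA catabolism genes lay above it. All 49 chloroplast-encoded genes lay below it, with a median log2 difference of -2.14, and 10 chloroplast genes gave the lowest values: rps2, atpA, atpB, psbZ, ccsA, psaB, matK, atpE, atpH and ndhD, from -3.81 to -3.16. Their spread in *opr3* was large, with 385 ± 354 for rps2 and 1351.1 ± 1480 for atpA. The list median was 7.91, 8.01 and 9.22 on the untreated *opr3* arrays, the last scanned on the day with the high values, and 5.99 on the Ws array, which has no scan-day record here, and 8 of 10 mitochondrion-encoded genes also lay below the *opr3* range. With a signal of at least 100 and a change of at least 2-fold, 660 probe sets were higher and 141 lower in Ws and outside the *opr3* range, and 65% of tested probe sets lay outside that range, where chance gives 50%. Of the 660, 637 were called higher at 22 h after JA and 428 at 22 h after OPDA, counts that use the same *opr3* arrays on both sides and so have no plain expectation. For Ws and OPDA at 22 h, r = 0.57 across probe sets was reached by 31 of 100 simulated unchanged sets, while the covariance of 0.171 lay above their highest, 0.150. JA over OPDA at 22 h shares no array with the Ws difference, and there 271 of the 660 were called higher, where 42.9 would be expected if independent (r = 0.68, reached by 1 of 100 simulated sets).

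**Figure D3:**
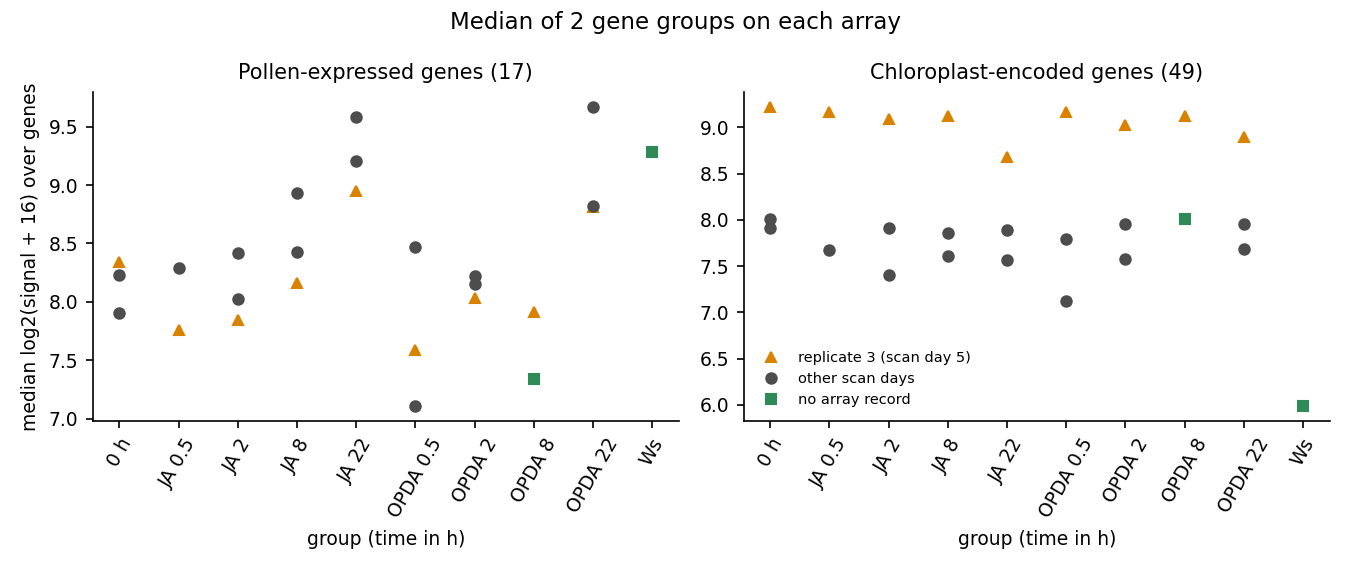
Points show the median log2(signal + 16) on each array over 17 pollen-expressed genes and over 49 chloroplast-encoded genes, by group, with symbols for the replicate 3 arrays of scan day 5, other scan days and arrays without a record. In 9 of 9 groups the scan day 5 array has the highest chloroplast-encoded median, and the Ws array lies below the untreated arrays for these genes.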

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

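The tests of time, of a slow response to OPDA, of scan day, of green tissue in every group, of mitochondrion-encoded genes, of abundant transcripts, of simulated sets that keep replicate numbers and of relabellings within replicate numbers were chosen after the results were seen. The comparison that shares no array was added after the data were examined but before its own result was seen.

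The difference between JA and OPDA changed over time by a limma test of the change itself, in 27 probe sets from 0.5 to 2 h, 217 from 2 to 8 h and 752 from 8 to 22 h. Between 8 and 22 h, 52 probe sets were called in opposite directions at the 2 times, 39 higher after JA at 8 h and lower at 22 h, and 13 the other way. The genes named next were picked from these outside the naming rule. AT3G01350 had means of 898 after JA and 279 after OPDA at 8 h, and 283 and 706 at 22 h (adjusted p of the change 0.00096). The glucosinolate transporter GTR2 had 990 and 316 at 8 h, and 339 and 645 at 22 h (adjusted p of the change 0.0012). The metallothionein MT1C had 152 and 279 at 8 h, and 1102 and 301 at 22 h (adjusted p of the change 2.2e-05).

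Many transcripts, ANX1 and ATA27 among them, moved the same way at 22 h after OPDA and after JA. Shared untreated arrays as the whole source are argued against: OPDA 22 h minus OPDA 0.5 h and JA 22 h minus untreated, which share no array, had a correlation across probe sets of 0.67, narrowly above the highest of 100 simulated unchanged sets, 0.65, or 0.61 (mean 0.34) where the sets kept what arrays of 1 replicate number share, while part of the overlap in counts may still come from them. Time since treatment or harvest cannot be told apart from an effect of OPDA, as 2266 probe sets were called between OPDA 0.5 h and OPDA 22 h and no mock-treated arrays bear on them. A slow JA-like response to OPDA also stays open. In 195 early JA probe sets the shift from the 0.5 h to the 22 h arrays was 0.65 for OPDA and 0.73 for JA. The ratio of these shifts was 0.89 (95% interval 0.49 to 1.29), which time alone could give as well. The JA shift leaves out what had already changed at 0.5 h, so the ratio does not show a nearly full JA response to OPDA. From untreated arrays the shift of these probe sets was 0.67 for OPDA at 22 h, 1.14 for JA at 22 h and 1.63 for JA at 8 h.

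Chloroplast-encoded transcripts were higher on untreated replicate 3 than on replicates 1 and 2. The array of the same scan day was highest in 9 of 9 groups, which is consistent with a batch that took in every replicate 3 array, and it was also highest in 9 of 9 groups in the median over 10 mitochondrion-encoded genes, with 6.56 against 6.38 and 6.37 in untreated stamens. Nuclear photosynthesis genes, which have a high baseline, rose by 0.29 where chloroplast-encoded genes rose by 1.19 in that sample, a ratio of 0.25, and over all groups the ratio was 0.18 (SE 0.03). These ratios leave more green tissue open as a source of part of the chloroplast-encoded rise, in that sample and in other replicate 3 samples. The nuclear and chloroplast-encoded rises did not run in step across groups. They were 0.04 and 1.19 for OPDA at 8 h, 0.11 and 1.60 for OPDA at 0.5 h, and 0.40 and 1.24 for JA at 8 h. Whether more green tissue would also bring the mitochondrion-encoded rise was not tested. Green tissue is weighed here as a mixed sample, as the design names no biological difference between replicates of 1 group.

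At 22 h after JA more probe sets fell than rose, with 33.5% of calls higher, though the share was 57.5% among calls with a change of at least 2-fold. Whether the authors' scaling accounts for part of it cannot be told from other scalings. The share was 45.3% under scaling to the 75th percentile, 40.7% under quantile normalization and 50.4% after median centring. The 75th percentile was 131.4 to 140.2 on JA 22 h arrays and 145.9 to 150.4 on untreated ones. Scaling to it therefore lifts the JA 22 h changes by construction. Quantile normalization gives all arrays 1 distribution, and median centring sets the median change to 0. A larger share of rises under these settings is thus no separate support. Whether a few abundant transcripts took up signal cannot be told: the brightest 10% of probe sets held 47.2% of the trimmed signal at 22 h after JA and 43.9% in untreated arrays, but arrays scaled to 1 trimmed mean with a lower median hold a larger share there by construction. A change in the stamens after JA stays open as the biological explanation.

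For each comparison of 3 against 3 arrays, 10 splits are too few for a share under 0.05, and 1 of the 10, the real split, gave a count as large. The real count and the highest of the others were 312 and 0 for JA at 2 h, 1407 and 125 for JA at 8 h, 5552 and 2 for JA at 22 h, 1 and 0 for OPDA at 0.5 h, 3 and 0 for OPDA at 2 h, 1628 and 0 for OPDA at 22 h, 266 and 0 for JA over OPDA at 2 h, and 2624 and 7 for JA over OPDA at 22 h. For JA over OPDA averaged over the times, 1 of 100 relabellings within times, the real one, gave 2056 calls, and the highest of the others gave 854. Where labels were swapped only between arrays of 1 replicate number, again 1 of 100, the real one, gave as many, and the highest of the others gave 1179. The share stayed under 0.05 with both kinds of relabelling, which makes chance unlikely there but does not exclude it. Among 100 simulated sets with no change, 2 held any call for this comparison, and the highest count was 1730.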

How the results depend on the processing

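The alternatives with the duplicated array kept, moved to another replicate number or moved to another scan day, median centring, and the overlaps without a treated array were chosen after the data were seen. Of the alternatives for the named genes, 1343 kept direction and call, 58 lost the call and 0 reversed, over 62 results. These genes were picked for large changes between groups that do not overlap, so leaving out an array could not reverse them. The 0 is therefore no measure of robustness. For counts and overlaps, 306 values stayed within 1.5 times (or the spread), 84 moved further and 1, a correlation, changed sign. The cause of each change below was not tested, apart from the fewer arrays or probe sets that some settings use. Means near or under the added 16, such as those of SWEET14 before 22 h, give log2 changes smaller than the ratio of signals.

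A pseudocount of 64 called 6 for OPDA at 2 h, and no intensity trend 5. A mean signal of at least 100, which tests fewer probe sets, called 9 for JA at 0.5 h, 0 for OPDA at 0.5 h and 1 for OPDA at 2 h. A fit to the compared groups alone, with fewer arrays behind the spread, called 0 for JA at 0.5 h, 650 for JA at 8 h, 0 for OPDA at 0.5 h, 0 for OPDA at 2 h and 469 for OPDA at 22 h, and for JA over OPDA 3 at 0.5 h, 448 at 8 h and 1601 at 22 h. Array weights called 35 for JA at 0.5 h, 491 for JA at 2 h, 4 for OPDA at 0.5 h, 7 for OPDA at 2 h and 19 for JA over OPDA at 0.5 h. With the duplicated array kept as 2 samples 40 were called for JA at 0.5 h, 7 for OPDA at 2 h and 30 for JA over OPDA at 0.5 h. A change of at least 2-fold, a stricter limit, left 183, 510 and 1805 for JA at 2, 8 and 22 h, 640 for OPDA at 22 h, 141, 504 and 883 for JA over OPDA at 2, 8 and 22 h, and 148 for the average.

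The labels do not say that replicate numbers pair the samples. Deviations of arrays with 1 replicate number correlated above 0.1 in 22 of 32 pairs, and in all pairs of 5 of 12 comparisons, and 22 of 25 arrays correlated best with an array of their own number in another group, a hint from the data and not the design. The replicate block called 2202 for JA at 8 h, 5 for OPDA at 2 h, 2791 for OPDA at 22 h and 466 for JA over OPDA at 2 h, and 2237, 5, 2802 and 476 with the duplicated array as number 2. The scan-day block called 2146 for JA at 8 h, 0 for OPDA at 0.5 h, 2770 for OPDA at 22 h and 540 for JA over OPDA at 8 h. With the duplicated array on the other day it called 9 for JA at 0.5 h, 2178 for JA at 8 h, 0 for OPDA at 0.5 h, 0 for OPDA at 2 h, 2800 for OPDA at 22 h and 543 for JA over OPDA at 8 h. The chip-lot block called 2 for OPDA at 0.5 h, 0 for OPDA at 2 h and 460 for JA over OPDA at 8 h.

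With 1 array left out in turn, the counts ran from 7 to 20 for JA at 0.5 h, from 861 to 1599 for JA at 8 h, from 0 to 2 for OPDA at 0.5 h, from 0 to 6 for OPDA at 2 h and from 213 to 2164 for OPDA at 22 h. For JA over OPDA they ran from 5 to 18 at 0.5 h and from 416 to 1188 at 8 h. The number called the same way after JA and OPDA ran from 0 to 1 at 0.5 h, 0 to 6 at 2 h and 177 to 1733 at 22 h, and the correlation across probe sets from 0.26 to 0.59 at 2 h and from -0.01, without OPDA 8 h replicate 3, to 0.41 at 8 h, where it was 0.14 with all arrays. Of 55 list calls, 28 held without each array of the compared groups and 27 were lost without at least 1, a check added after the data were seen. Where this leaves 1 array in a group, that array is taken to vary like the others.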

Other observations

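The families added by symbol were chosen after the probe names but before any fold change was seen, apart from nuclear photosynthesis genes, and comparisons of Ws with the compounds that share no array were chosen after the data were examined, and no explanation is offered for the values below.

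Further gene groups at 22 h after JA went both ways or were called in part, with no list called by limma's camera. UDP-glycosyltransferases had 2 of 19 higher and 4 lower (adjusted p = 0.66), serine carboxypeptidase-like genes 3 of 15 higher and 5 lower (0.75), beta-glucosidases 1 of 9 higher and 3 lower (0.57), and aldehyde dehydrogenases 1 of 8 higher and 4 lower (0.24). Ubiquitin-conjugating enzymes had 6 of 10 lower (0.46) and ubiquitin-specific proteases 4 of 12 lower (0.64). Glutathione S-transferases had 3 of 7 higher (0.071) and TBL genes 4 of 12 higher and 1 lower (0.071). Defensin-like genes had 1 of 5 higher and 1 lower (0.57), autophagy genes 1 of 10 higher and 2 lower (0.56), mitochondrion-encoded genes 0 of 10 called (0.36), chloroplast-encoded genes 1 of 49 lower (0.92), and cell wall loosening genes 1 of 3 higher, EXPA8, also when adjusted over the list alone (0.19).

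Lists with fewer than 3 tested members were counted without a list test. At 22 h after JA, GSTU25 of the electrophile and detoxification list rose from 17.5 ± 13.7 to 101 ± 14.3 (n = 3 each) and AT4G01870 fell by 0.80. GI of the clock list (log2 change -0.58), SPT of the carpel and ovule list (-0.75), ROF2 of the heat shock list (-0.95) and WES1 of the gibberellin and auxin list (-0.60) were also lower, while MYC3 of JA signalling (limma adjusted p = 0.63), DFR of the flavonoid list (0.41), IGPS of the tryptophan list (0.88) and BCAT4 of the aliphatic glucosinolate list (0.20) were not called. STZ of the early wound and touch list was called lower at a log2 change of -0.50. Of the GH3 amido synthetases picked by symbol, GH3.3 and GH3.17 (0.91) were higher, while WES1 above, also named GH3.5, was lower. Both cytochromes P450 were lower, and of the AUX/IAA and YUC genes 1 of 2 was lower. JAZ repressors, stamen MYB factors, aquaporins, cell cycle, floral organ identity and senescence genes had 0 tested members and were not analysed here.

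Across probe sets, which are not independent, Ws minus untreated and JA 22 h minus OPDA 22 h, which share no array, had r = 0.68, reached by 1 of 100 simulated unchanged sets. Ws minus untreated had r = 0.83 with JA 22 h minus untreated (reached by 3 of 100) and r = 0.57 with OPDA 22 h minus untreated (reached by 31 of 100), with covariances of 0.430 and 0.171 against at most 0.135 and 0.150 in the simulated sets. In Ws, THI2.1 stood at 1883 against 387 ± 46.9 (n = 3) in *opr3*, ADPG1 at 844.8 against 160 ± 62.6 and JMT at 390.4 against 148 ± 68.0. Of 10 mitochondrion-encoded genes, 8 lay below the *opr3* range in Ws and 1 above it.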
